A study of Homo sapiens with 60 samples.

How the data were processed

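RNA from SW1783 cells, grown in L-15 medium and treated for 24 h, was sequenced as directional messenger RNA libraries on an MGI instrument with paired-end reads. Per the labels RNA of integrity number above 7 was used, and libraries with too little RNA were left out before deposition. The deposited values analysed are expected counts per gene, estimated by the authors with RSEM, with no normalization. The labels name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a, RSEM 1.3.3 and the build GRCh38, without their roles, the annotation release, filters or the strand setting. Per the labels vehicle was 0.1% DMSO in the sample records and a higher share in the series text, and it could not be settled which applies. The labels do not say whether replicates are separate cultures or splits of 1 culture. The labels also describe hot-water extracts, which the analysed libraries do not hold. The table had 60675 gene identifiers and 60 libraries, each assigned to its extract, dose and replicate by its name, with none unassigned. Symbols were given for 41209 identifiers (67.9%), and positions, gene types and median transcript lengths came from GENCODE release 29 by Ensembl identifier, which held 18468 of the 18601 tested genes (99.3%).

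Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at a minimum count of 10 and a minimum total of 15 on the groups, scaled by TMM, and fitted in 1 quasi-likelihood model of all 60 libraries with a mean per group (robust dispersions, 37 residual degrees of freedom). Each high, medium and low dose was compared with vehicle, each high with its low dose, Okbyeongpung-san pooled over doses with vehicle, and Soyo-san high with Menthae Herba high, all two-sided. Adjusted p is Benjamini-Hochberg over the 18601 genes of a comparison, and a gene was called at adjusted p under 0.05. SE is that of the log2 fold change from the quasi-likelihood F, and levels are TMM-scaled CPM with the SD over libraries. Further contrasts of high minus low dose between extracts were added after the data were examined. Medium and low doses were given as counts and as values of genes named at the high dose. Where a refit without 1 library ended a call, the highest adjusted p over those refits is given.

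Fixed lists of genes, 29 in number, covered NRF2, AhR, ATF4, LXR, p53, FOXO, glucocorticoid, YAP and SRF targets, endoplasmic reticulum and heat shock chaperones, cholesterol and fatty acid synthesis, G2/M, DNA replication, NF-kB, interferon, hypoxia, collagens, immediate early genes, metallothioneins, lysosome, mitochondrially encoded and ribosomal protein genes. Marker lists covered astrocytes and glioma, neurons, leukocytes, endothelium, epithelium and hepatocytes. Lists with at least 3 tested members (28) were tested with camera in limma 3.58.1, at the preset correlation of 0.01 between genes, two-sided, and adjusted over 28 lists and 7 extracts together for each family and over 28 lists for Okbyeongpung-san. Calls were repeated with a correlation estimated per list and with fry. Named genes had adjusted p under 0.05. All but list members also had a mean log2 CPM of at least 2 and no overlap of libraries between the groups. Named were the 8 largest rises and falls of each high dose and the 2 called members with the largest change of each called list. The 3 largest rises and falls from low to high dose and the 4 of Okbyeongpung-san were also named, passing over genes without a symbol. Members of lists named because 5 or fewer moved one way were chosen after their values were seen. Formulas and herbs were compared by Pearson r across genes of the high minus low log2 fold changes. Constituents were taken from the textbook recipes, Polygalae Radix and Aucklandiae Radix in Guibi-tang, Menthae Herba in Soyo-san and Saposhnikoviae Radix in Okbyeongpung-san.

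The transcript-length slope of a library was fitted over 10019 genes with a mean log2 CPM of at least 3 (deviation of log2 CPM, prior count 2, from the vehicle mean), and libraries below -0.150 were called length-tilted. Principal components used the 2000 most variable genes. Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a replicate block, the compared groups alone, each library left out in turn, and library-name set by replicate as a block for high against low dose. Fits without the length-tilted libraries, with the length slope as a covariate and with libraries thinned to the smallest total were added after the data were examined. On simulated data with known changes the test called 25.4%, 55.2% and 81.8% of genes changed 1.5, 2 and 4-fold with 3 libraries against 3. With 2 against 3 it called 25.4%, 49.3% and 86.4%. Of the calls made, 3.36% and 6.56% fell on unchanged genes (18379 of 18601), and 1 raised list was called with 0 others. The simulation drew each gene independently, without a length tilt or a difference between library-name sets. It therefore cannot give the error rates of genes or lists in the real data. Pairs of replicates had r between 0.924 and 0.993 over 48 pairs, and their spread exceeded counting error, with chi-square per degree of freedom from 3.02 to 379. Groups had at most 3 libraries, so no library was tested as an outlier and none was left out. No adjustment for library-name set was possible in comparisons with vehicle.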

Results

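SW1783, an established human astrocytoma line, was sequenced after 24 h with ethanol extracts of 4 single herbs or 4 traditional multi-herb formulas, in 60 libraries of messenger RNA. The single herbs were Polygalae Radix (root of Polygala), Aucklandiae Radix (root of Aucklandia), Menthae Herba (mint) and Saposhnikoviae Radix (root of Saposhnikovia), and the formulas were Saengmaek-san, Guibi-tang, Soyo-san and Okbyeongpung-san. Each extract was given at 3 doses, high, medium and low, each 5 times below the one before. The doses were 500, 100 and 20 µg/mL for 6 extracts, 160, 32 and 6.4 µg/mL for Aucklandiae Radix, and 30, 6 and 1.2 µg/mL for Polygalae Radix, with high doses set by the concentration that inhibits growth by 20%. Vehicle (DMSO) had 3 libraries, and each dose had 3 for Menthae Herba, Saposhnikoviae Radix, Saengmaek-san and Guibi-tang, 2 for Polygalae Radix, Aucklandiae Radix and Soyo-san, and 1 for Okbyeongpung-san. Library totals ran from 19031094 to 37686975 expected counts, and from 25186538 to 26477754 in the vehicle libraries. The labels put forward the gene expression profile of each extract, and how a formula relates to its constituent herbs, as the subject of the series. Library names placed the samples in sets, 11 for Polygalae and Aucklandiae Radix, 12 for Menthae Herba and Saposhnikoviae Radix, 13 for Saengmaek-san and Guibi-tang, 14 for Soyo-san and Okbyeongpung-san, and D1 for vehicle. A set and its extracts therefore cannot be told apart from each other in a comparison with vehicle, and the same 3 vehicle libraries served all of those comparisons. High against low dose compares libraries within 1 set.

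Short and long transcripts shifted against each other in some libraries. The slope of each gene's log2 deviation from the vehicle mean on the log2 of its median annotated transcript length lay below -0.15 in 10 of 60 libraries, meaning relatively more counts on short transcripts. These were Saposhnikoviae Radix high replicate 2 (-0.448), low replicate 2 (-0.198) and low replicate 3 (-0.327), Menthae Herba high replicate 3 (-0.345), replicate 1 of each Saengmaek-san dose, Guibi-tang medium and low replicate 2, and Okbyeongpung-san high replicate 1 (-0.396). The first principal component, with 27.0% of the variance, followed this slope across the 60 libraries (Pearson r = -0.943, Spearman rho = -0.851, each with two-sided permutation p = 1e-05, the smallest that the permutations can give, for the 1 relation tested). Without the 2 libraries farthest from the median slope r was -0.906, and over the 50 libraries with a slope above the limit it was -0.697. Within sets 11, 12, 13 and 14, r was -0.475 (n = 12), -0.984 (n = 18), -0.934 (n = 18) and -0.998 (n = 9), and set D1 held too few libraries. Mitochondrially encoded genes took 10.2% ± 0.114 of the counts in vehicle (SD, n = 3), 15.5% ± 5.28 at the high dose of Polygalae Radix (SD, n = 2) and 5.62% ± 2.16 at that of Aucklandiae Radix (SD, n = 2). The low doses of Menthae Herba, Guibi-tang and Aucklandiae Radix lay under vehicle (6.77%, 6.61% and 7.24%), and that of Polygalae Radix at 10.1% ± 2.96 (SD, n = 2).

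**Figure D1:**
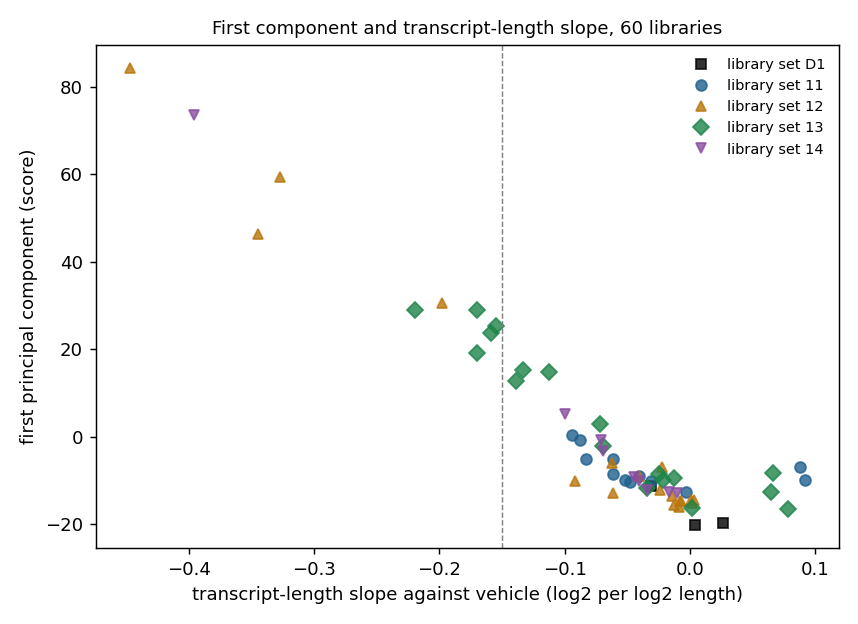
First principal component (arbitrary units) of each of the 60 libraries against its transcript-length slope (log2 deviation from the vehicle mean per log2 of transcript length), 1 point per library, coloured by library-name set, with a dashed line at -0.15. The 10 libraries left of the line reach -0.448, and the vehicle libraries lie between -0.0310 and 0.0270.

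The high doses of Guibi-tang and Polygalae Radix changed the most genes of the 18601 tested, with 9290 and 8842 called against vehicle. Aucklandiae Radix followed with 5875, Menthae Herba with 3884 and Saengmaek-san with 2844, while Saposhnikoviae Radix had 1405 and Soyo-san 360. At the medium dose the counts lay between 36 for Soyo-san and 997 for Guibi-tang. Within a set, high against low dose called 9467 genes for Guibi-tang, 8441 for Polygalae Radix, 4239 for Aucklandiae Radix, 2561 for Menthae Herba, 908 for Saengmaek-san, 61 for Soyo-san and 29 for Saposhnikoviae Radix. Collagen and matrix genes were lower as a list at the high dose of all 7 extracts tested at single doses, and the call held with an estimated correlation for Polygalae Radix, Menthae Herba and Guibi-tang. Between high and low dose, with no vehicle library, that list did not pass for Saposhnikoviae Radix (adjusted p = 0.145) or Saengmaek-san (adjusted p = 0.0509). The NRF2 targets (antioxidant and detoxifying enzymes) were higher as a list for Aucklandiae Radix, Menthae Herba, Saposhnikoviae Radix, Saengmaek-san and Soyo-san, and the call held with an estimated correlation for Soyo-san. Of 28 fixed lists the high dose called 20, 14, 13, 8, 10, 14 and 10 against vehicle for Polygalae Radix, Aucklandiae Radix, Menthae Herba, Saposhnikoviae Radix, Saengmaek-san, Guibi-tang and Soyo-san, of which 10, 5, 6, 2, 3, 8 and 3 held with an estimated correlation. High against low dose called 18, 14, 13, 8, 15, 16 and 11 lists in the same order, of which 10, 7, 7, 5, 7, 7 and 5 held.

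**Figure D2:**
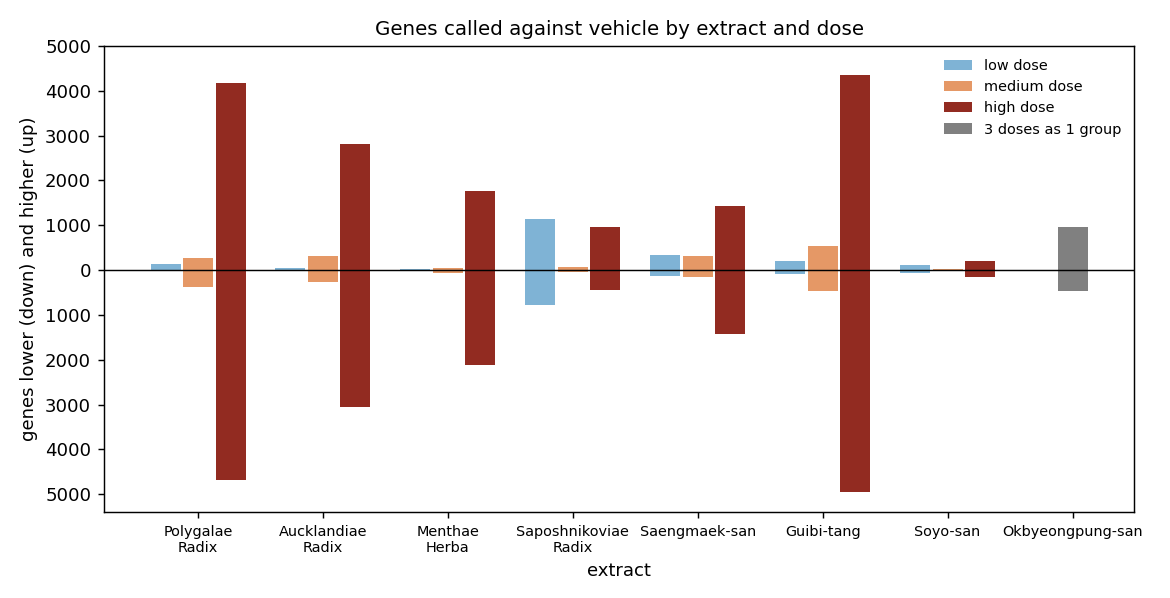
Genes called higher or lower than vehicle (edgeR, adjusted p under 0.05, number of genes) at each dose of 7 extracts and for the pooled libraries of Okbyeongpung-san. Guibi-tang and Polygalae Radix reach 9290 and 8842 genes at the high dose, and Saposhnikoviae Radix has more at the low dose (1899) than at the medium dose (94).

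Polygalae Radix at its high dose was tested for what the root extract alone did to the cells, and most listed matrix, contractile target and chaperone genes were lower. TNC (ENSG00000041982, chromosome 9 from 115019578 to 115118257), encoding the matrix glycoprotein tenascin C, was at 33.1 ± 3.22 CPM (SD, n = 2) against 860.4 ± 31.6 (SD, n = 3) in vehicle (log2 fold change -4.70, SE 0.44, adjusted p = 4.8e-12). COL1A2 (ENSG00000164692, chromosome 7 from 94394561 to 94431232), a chain of type I collagen, fell from 1930.1 ± 66.8 CPM (SD, n = 3) to 138 ± 1.35 (SD, n = 2), at adjusted p = 1.8e-19. Among the rises, IFIT2 (ENSG00000119922, chromosome 10 from 89283694 to 89309276), an interferon-induced gene, was at 67.1 ± 4.19 CPM (SD, n = 2) against 7.19 ± 0.920 (SD, n = 3) in vehicle (log2 fold change 3.22, SE 0.24, adjusted p = 8.5e-15), and GDF15 (ENSG00000130513, chromosome 19 from 18374731 to 18389176), a stress-induced cytokine, at 34.1 ± 0.257 CPM (SD, n = 2) against 3.74 ± 0.208 (SD, n = 3) (log2 fold change 3.18, SE 0.42, adjusted p = 3.2e-08). In all, 4163 genes were higher and 4679 lower. The 8 largest rises, with log2 fold changes of 2.37 to 3.22, were IFIT2, GDF15, IGFN1, RND3, BCL7A, TBX2, PLD6 and RPP25. The 8 largest falls, with log2 fold changes of -5.37 to -3.52, were the readthrough locus ATP6V1G2-DDX39B, TNC, ITGB4, COL1A2, ANPEP, MAGED1, ABI3BP and COL6A3. At the medium dose TNC had a log2 fold change of -1.31 (adjusted p = 0.0321), COL1A2 of -0.78 (adjusted p = 0.00455) and IFIT2 of 1.37 (adjusted p = 2.3e-04). GDF15 had 1.16 (adjusted p = 0.144) and did not pass.

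Among 22 collagen and matrix genes, 0 rose, 22 fell and 0 did not pass, the same adjusted over the list alone. For collagen and matrix genes the median log2 fold change was -2.55 (adjusted p = 1.2e-19, adjusted p = 0.0269 with an estimated correlation). Of 16 YAP and SRF contractile targets, 11 fell, 1 (AMOTL2) rose and 4 passed neither way, the same adjusted over the list alone. With these YAP and SRF contractile targets the median log2 fold change was -1.31 (adjusted p = 4.6e-05, adjusted p = 0.00664 with an estimated correlation). TAGLN, an actin-binding protein, had a log2 fold change of -2.38. Endoplasmic reticulum chaperone genes had a median log2 fold change of -1.06 (adjusted p = 3.3e-05, adjusted p = 0.0221 with an estimated correlation). Of 16, 2 (XBP1 and DNAJB9) were higher, 11 lower and 3 not past the threshold, the same adjusted over the list alone. HSPA5, the main chaperone of that compartment, had a log2 fold change of -3.12 (adjusted p = 3.3e-23). Of 16 heat shock chaperone genes, 10 fell, 0 rose and 6 passed neither way, the same adjusted over the list alone. With these heat shock chaperone genes the median log2 fold change was -1.21 (adjusted p = 2.1e-05, adjusted p = 0.0150 with an estimated correlation). HSP90AA1 had a log2 fold change of -2.50 and HSPD1 of -1.77. The list of cholesterol biosynthesis genes (adjusted p = 2.6e-07, adjusted p = 0.00340 with an estimated correlation) had a median log2 fold change of -1.07. Its calls were 0 of 24 higher, 20 lower and 4 neither, the same adjusted over the list alone. Among 11 fatty acid synthesis genes, 0 rose, 11 fell and 0 did not pass, the same adjusted over the list alone. For fatty acid synthesis genes the median log2 fold change was -1.05 (adjusted p = 2.2e-06, adjusted p = 0.0269 with an estimated correlation). ACLY and FASN had log2 fold changes of -2.39 and -2.19.

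Hypoxia and glycolysis genes had a median log2 fold change of -0.99 (adjusted p = 1.6e-05, adjusted p = 6.8e-04 with an estimated correlation). Of 20, 1 (ADM) was higher, 13 lower and 6 not past the threshold, or 2 higher and 13 lower adjusted over the list alone. ALDOC, a glycolytic aldolase, and CA9, a carbonic anhydrase, had log2 fold changes of -3.53 and -3.49. Glucocorticoid targets had a median log2 fold change of 0.90 (adjusted p = 0.0206, adjusted p = 0.0455 with an estimated correlation). Of 9, 6 were higher, 2 (FKBP5 and ANGPTL4) lower and 1 not past the threshold, the same adjusted over the list alone.

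Between the high and the low dose 3772 genes were higher and 4669 lower, with GDF15, IFIT2 and IGFN1 as the 3 largest rises (log2 fold changes 2.76 to 3.02) and ATP6V1G2-DDX39B, TNC and ITGB4 as the 3 largest falls (-5.57 to -3.86). Of 53 named genes, KRT19 alone lost the call in a refit without 1 library (adjusted p = 0.0585 without high replicate 3). Against vehicle, the medium dose called 642 genes and the low dose 154. All 5 refits without 1 library moved both counts by more than 1.5 times.

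Aucklandiae Radix at its high dose was compared with vehicle to see the response to this root alone, and mitotic genes were lower as a list while HMOX1 was higher. HMOX1 (ENSG00000100292, chromosome 22 from 35380361 to 35394214), encoding haem oxygenase 1, was at 1270.0 ± 28.3 CPM (SD, n = 2) against 59.3 ± 1.81 (SD, n = 3) in vehicle (log2 fold change 4.42, SE 0.39, adjusted p = 4.5e-12). ANGPTL4 (ENSG00000167772, chromosome 19 from 8363289 to 8374373), a secreted inhibitor of lipoprotein lipase, was at 283 ± 15.5 CPM (SD, n = 2) against 13.9 ± 2.33 (SD, n = 3) (log2 fold change 4.34, SE 0.51, adjusted p = 7.5e-09). KIF20A (ENSG00000112984, chromosome 5 from 138178719 to 138187715), a mitotic kinesin, was at 12.8 ± 1.90 CPM (SD, n = 2) against 143 ± 6.54 (SD, n = 3) (log2 fold change -3.48, SE 0.24, adjusted p = 7.2e-15). The test called 2819 genes higher and 3056 lower. HMOX1, ANGPTL4, TM4SF19, THBD (thrombomodulin), SLCO4A1, TMEM171, KCNC4 and MT1E were the 8 largest rises, at log2 fold changes of 2.62 to 4.42. TUBA1B-AS1, VAV3, NEURL1B, DIO2 (a deiodinase that activates thyroid hormone), CYP24A1 (which degrades vitamin D), LYPD1, KIF20A and ST6GALNAC5 were the 8 largest falls, at -9.42 to -3.42. TUBA1B-AS1, an antisense locus of a tubulin gene, stood at 136 ± 0.627 CPM in vehicle (SD, n = 3) and 0.195 ± 0.155 here (SD, n = 2). Its fitted log2 fold change rests on few counts and was also -9.17 at the low dose (adjusted p = 0.154). This locus led the falls from vehicle of Menthae Herba, Saengmaek-san and Guibi-tang too, but was no named fall from low to high dose. At the medium dose HMOX1 had a log2 fold change of 0.59 (adjusted p = 0.503), ANGPTL4 of 1.52 (adjusted p = 0.0754) and THBD of 0.91 (adjusted p = 0.00512).

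G2/M cell cycle genes had a median log2 fold change of -1.63 (adjusted p = 5.5e-27, adjusted p = 1.1e-04 with an estimated correlation). Of 22, 0 were higher, 22 lower and 0 not past the threshold, the same adjusted over the list alone. Of 22 NRF2 targets, 2 (TKT and AKR1B10) fell, 16 rose and 4 passed neither way, or 3 lower and 16 higher adjusted over the list alone. With these NRF2 targets the median log2 fold change was 1.00 (adjusted p = 5.3e-07, adjusted p = 0.116 with an estimated correlation). AKR1C1, a reductase with close paralogs, had a log2 fold change of 2.41. Among 23 ATF4 stress response genes, 14 rose, 1 (STC2) fell and 8 did not pass, or 15 higher and 1 lower adjusted over the list alone. For ATF4 stress response genes the median log2 fold change was 0.81 (adjusted p = 2.4e-06, adjusted p = 0.0233 with an estimated correlation). ATF3 and ASNS had log2 fold changes of 1.72 and 1.68. The list of immediate early and MAPK feedback genes (adjusted p = 1.5e-06, adjusted p = 0.0269 with an estimated correlation) had a median log2 fold change of 0.74. Its calls were 10 of 20 higher, 1 (JUNB) lower and 9 neither, or 11 higher and 1 lower adjusted over the list alone. DUSP5 and DUSP6, phosphatases that act on ERK, had log2 fold changes of 2.25 and 1.87. Interferon response genes had a median log2 fold change of -0.65 (adjusted p = 2.1e-05, adjusted p = 0.0266 with an estimated correlation). Of 21, 0 were higher, 12 lower and 9 not past the threshold, the same adjusted over the list alone. IFI44L had a log2 fold change of -2.24 and OAS3 of -1.99.

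From low to high dose 1800 genes were higher and 2439 lower, with HMOX1, ANGPTL4 and TM4SF19 leading the rises (log2 fold changes 3.52 to 4.21) and DIO2, LYPD1 and NEURL1B the falls (-3.80 to -3.52). Of 41 genes named for the high dose, 6 lost the call in at least 1 refit without 1 library, namely 6 without high replicate 3, 3 without high replicate 2, and 1 each without vehicle replicates 1 and 2. For this root the medium dose called 579 genes and the low dose 62. Both counts moved by more than 1.5 times in every one of the 5 refits without 1 library, with ranges of 86 (without medium replicate 2) to 307 and 1 (without low replicate 2) to 11.

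Menthae Herba at the high dose raised genes of the amino acid and integrated stress response and lowered matrix genes, in the comparison with vehicle that tests the herb alone. CHAC1 (ENSG00000128965, chromosome 15 from 40952962 to 40956519), a glutathione-degrading enzyme, was at 55.8 ± 9.90 CPM (SD, n = 3) against 7.54 ± 0.560 (SD, n = 3) in vehicle (log2 fold change 2.89, SE 0.19, adjusted p = 1.1e-14). DDIT4 (ENSG00000168209, chromosome 10 from 72273920 to 72276036), an inhibitor of mTORC1 signalling, was at 377 ± 94.4 CPM (SD, n = 3) against 69.5 ± 6.08 (SD, n = 3) (log2 fold change 2.44, SE 0.19, adjusted p = 8.7e-13). SESN2 (ENSG00000130766, chromosome 1 from 28259527 to 28282491), another stress-induced inhibitor of mTORC1, was at 112 ± 3.21 CPM (SD, n = 3) against 26.0 ± 0.653 (SD, n = 3) (log2 fold change 2.11, SE 0.08, adjusted p = 8.7e-24). HSPG2 (ENSG00000142798, chromosome 1 from 21822245 to 21937297), encoding the matrix proteoglycan perlecan, was at 74.2 ± 28.4 CPM (SD, n = 3) against 492 ± 14.0 (SD, n = 3) (log2 fold change -2.73, SE 0.32, adjusted p = 1.3e-08). Calls numbered 1764 higher and 2120 lower. The largest rises were ANGPTL4, CHAC1, DDIT4, TRIB3, SESN2, ADM2, GDF15 and PLIN2 (a lipid droplet protein), at log2 fold changes of 1.99 to 3.34. The largest falls, at -6.44 to -2.62, were TUBA1B-AS1, CEMIP (a hyaluronan-degrading protein), TENM2, HMCN1, HSPG2, FAT4, SLIT2 and VCAN (versican). None of CHAC1, DDIT4 and SESN2 passed at the medium dose, where their log2 fold changes were -0.08, -0.03 and 0.27 (adjusted p = 0.985, 0.998 and 0.0843).

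Of 23 ATF4 stress response genes, 0 fell, 18 rose and 5 passed neither way, the same adjusted over the list alone. With these ATF4 stress response genes the median log2 fold change was 1.19 (adjusted p = 2.4e-23, adjusted p = 2.2e-05 with an estimated correlation). The list of collagen and matrix genes (adjusted p = 4.9e-27, adjusted p = 0.00946 with an estimated correlation) had a median log2 fold change of -1.56. Its calls were 0 of 22 higher, 21 lower and 1 neither, or 0 higher and 22 lower adjusted over the list alone. COL6A3 and TNC had log2 fold changes of -2.49 and -2.41. YAP and SRF contractile targets had a median log2 fold change of -0.64 (adjusted p = 2.5e-09, adjusted p = 8.7e-05 with an estimated correlation). Of 16, 0 were higher, 10 lower and 6 not past the threshold, the same adjusted over the list alone. ANKRD1 had a log2 fold change of -1.58. Among 20 hypoxia and glycolysis genes, 11 rose, 1 (P4HA1) fell and 8 did not pass, or 12 higher and 1 lower adjusted over the list alone. For hypoxia and glycolysis genes the median log2 fold change was 0.45 (adjusted p = 9.3e-08, adjusted p = 5.6e-05 with an estimated correlation). NDRG1 and ALDOC had log2 fold changes of 1.79 and 1.56.

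High replicate 3 had a transcript-length slope of -0.345. The count without it was 2459 in place of 3884, and 9 of 40 named genes lost the call, among them HMOX1 (log2 fold change 1.03, adjusted p = 0.0557), AKR1C1, SCD and RPS18. Without all length-tilted libraries the count was 5824 and 0 named genes lost the call. Other single libraries ended 1 call for high replicate 1, 2 for high replicate 2, and 2, 2 and 3 for vehicle replicates 1, 2 and 3. TUBA1B-AS1 lost it without high replicate 2 (adjusted p = 0.0675) and without high replicate 1. From low to high dose 948 genes were higher and 1613 lower, or 1487 in total without high replicate 3. ANGPTL4, CHAC1 and DDIT4 rose most (log2 fold changes 2.54 to 3.48) and CEMIP, TENM2 and HMCN1 fell most (-2.87 to -2.55). Its medium dose called 109 genes and the low dose 56. All 6 refits without 1 library moved both counts by more than 1.5 times. Ranges were 16 (without medium replicate 2) to 41 and 8 (without low replicate 3) to 34.

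Saposhnikoviae Radix at the high dose was compared with vehicle for the effect of this root alone, and the endoplasmic reticulum chaperone HSPA5 and SREBF1 were lower and CXCL8 was higher. HSPA5 (ENSG00000044574, chromosome 9 from 125234853 to 125241330) was at 1974 ± 469.7 CPM (SD, n = 3) against 3484 ± 54.1 (SD, n = 3) in vehicle (log2 fold change -0.82, SE 0.10, adjusted p = 1.5e-06). CXCL8 (ENSG00000169429, chromosome 4 from 73740506 to 73743716), encoding the chemokine interleukin 8, was at 7.24 ± 2.22 CPM (SD, n = 3) against 3.43 ± 0.537 (SD, n = 3) (log2 fold change 1.09, SE 0.21, adjusted p = 0.00236). SREBF1 (ENSG00000072310, chromosome 17 from 17810399 to 17837002), a transcription factor of lipid synthesis, was at 35.7 ± 3.02 CPM (SD, n = 3) against 62.9 ± 2.30 (SD, n = 3) (log2 fold change -0.82, SE 0.13, adjusted p = 1.3e-04). GCLM, a subunit of the enzyme that makes the glutathione precursor, had a log2 fold change of 0.55 (adjusted p = 0.00735). The test called 951 genes higher and 454 lower, with a strong length slope in high replicate 2 (-0.448). Leaving out vehicle replicate 1, 2 or 3 gave 403, 272 or 209 genes in place of 1405, leaving out high replicate 2 gave 248, and leaving out high replicate 1 or 3 gave 4215 or 4358. All length-tilted libraries left out gave 1882, and the slope as a covariate 1790. The named rises were BEST1, FMC1, THAP3, MALAT1, PET100, S100A13, BOLA2B and NAA38, at log2 fold changes of 1.38 to 1.90, and all 8 lost the call without high replicate 2, with adjusted p = 0.220 for BEST1 and 0.944 for THAP3. The named falls were the readthrough locus PEDS1-UBE2V1, EGR1, MT-ATP8, EGR3, MT-ND4L, PADI2, SALL2 and the pseudogene GTF2IP4, at -2.81 to -0.92. Of these PEDS1-UBE2V1 and PADI2 kept the call in every refit without 1 library. Of all 30 named genes 22 lost it in some refit, 22 without high replicate 2, 1 without high replicate 3, and 17, 19 and 21 without vehicle replicates 1, 2 and 3. HSPA5, PDIA4, CXCL8, SREBF1, GCLM and EGLN3 kept it in those refits, but a fit of the 6 compared libraries alone ended the call of all 30, a fit without the length-tilted libraries of 10 and 1 without the low-count filter of 18.

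The list of endoplasmic reticulum chaperone genes (adjusted p = 1.0e-04, adjusted p = 0.0269 with an estimated correlation) had a median log2 fold change of -0.24. Its calls were 0 of 16 higher, 5 (HSPA5, HERPUD1, HYOU1, PDIA4 and HSP90B1) lower and 11 neither, or 0 higher and 6 lower adjusted over the list alone. PDIA4, a disulfide isomerase, had a log2 fold change of -0.60. Of 20 hypoxia and glycolysis genes, 4 (PFKFB4, P4HA1, EGLN3 and BHLHE40) fell, 0 rose and 16 passed neither way, or 6 lower and 0 higher adjusted over the list alone. With these hypoxia and glycolysis genes the median log2 fold change was -0.14 (adjusted p = 1.7e-04, adjusted p = 0.00340 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase, had a log2 fold change of -0.63. NRF2 targets had a median log2 fold change of 0.50 (adjusted p = 5.2e-06, adjusted p = 0.156 with an estimated correlation). Of 22, 3 (GCLM, NQO1 and TXNRD1) were higher, 0 lower and 19 not past the threshold, or 12 higher and 0 lower adjusted over the list alone. NQO1 lost its call without high replicate 2 (adjusted p = 0.475). Among 18 NF-kB inflammatory genes, 4 (NFKBIA, LIF, CXCL1 and CXCL8) rose, 1 (TNFAIP2) fell and 13 did not pass, or 4 higher and 2 lower adjusted over the list alone. For NF-kB inflammatory genes the median log2 fold change was 0.25 (adjusted p = 0.0133, adjusted p = 0.0544 with an estimated correlation). CXCL1 had a log2 fold change of 1.72 and lost the call without vehicle replicate 3 (adjusted p = 0.126). NFKBIA and LIF were also called higher at the low dose of 4 of 7 extracts, with mean log2 fold changes of 0.44 and 0.34. The list of ribosomal protein genes (adjusted p = 2.4e-06, adjusted p = 0.344 with an estimated correlation) had a median log2 fold change of 0.68. Its calls were 9 of 20 higher, 0 lower and 11 neither, or 17 higher and 0 lower adjusted over the list alone. Short ribosomal protein transcripts moved with the length slope, and RPS14 and RPS9 lost their calls without high replicate 2 (adjusted p = 0.898 and 0.968). Without the 10 length-tilted libraries the ribosomal list did not pass (adjusted p = 0.410).

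High against low dose, within set 12, called 14 genes higher and 15 lower, and all 6 named ones lost the call in a fit of those 6 libraries alone. CPT1A, the enzyme that admits fatty acids to mitochondria, was at 62.7 ± 8.87 CPM (SD, n = 3) against 37.7 ± 1.16 (SD, n = 3) at the low dose (log2 fold change 0.74, SE 0.10, adjusted p = 5.8e-05), and HSPA5 had a log2 fold change of -0.57 (adjusted p = 0.00261). The other named genes of that comparison were TXNIP and PSMG3-AS1, which rose, and PLAT and CMC4, which fell. TXNIP lost its call without Saposhnikoviae Radix low replicate 2 (adjusted p = 0.238) and without low replicate 3 or high replicates 1 and 3, and CMC4 without Saposhnikoviae Radix low replicate 3 (adjusted p = 0.224). The count of 29 became 70 without high replicate 1, 218 without high replicate 2, 12 without low replicate 2 and 7 without low replicate 3. Endoplasmic reticulum chaperone genes between high and low dose had a median log2 fold change of -0.23 (adjusted p = 1.9e-08, adjusted p = 0.00193 with an estimated correlation). Of 16, 0 were higher, 3 (HSPA5, PDIA6 and PDIA4) lower and 13 not past the threshold, or 0 higher and 6 lower adjusted over the list alone. Of the lower doses, the medium dose called 94 genes and the low dose 1899. Both counts moved by more than 1.5 times in all 6 refits without 1 library. Ranges were 21 (without vehicle replicate 2) to 34 and 93 (without low replicate 3) to 5501.

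Saengmaek-san, a formula that holds none of the 4 single herbs, was compared with vehicle at its high dose, where TXNIP and inflammatory genes were higher and HTR2A was lower. TXNIP (ENSG00000265972, chromosome 1 from 145992435 to 145996600), which encodes a thioredoxin-binding protein induced by glucose, was at 105 ± 3.30 CPM (SD, n = 3) against 10.3 ± 0.587 (SD, n = 3) in vehicle (log2 fold change 3.34, SE 0.18, adjusted p = 1.9e-17). ARRDC4 (ENSG00000140450, chromosome 15 from 97960698 to 97973838), a related arrestin-domain gene, was at 18.3 ± 1.61 CPM (SD, n = 3) against 5.80 ± 0.202 (SD, n = 3) (log2 fold change 1.66, SE 0.20, adjusted p = 2.6e-07), and CXCL8 had a log2 fold change of 2.10 (SE 0.21, adjusted p = 5.9e-09). HTR2A (ENSG00000102468, chromosome 13 from 46831550 to 46897076), the serotonin 2A receptor, was at 2.18 ± 0.717 CPM (SD, n = 3) against 7.94 ± 1.19 (SD, n = 3) (log2 fold change -1.85, SE 0.22, adjusted p = 1.1e-07). TXNIP was at a log2 fold change of 0.35 at the medium dose (adjusted p = 0.229) and HTR2A at -0.72 (adjusted p = 0.0482). Here 1425 genes were higher and 1419 lower. TXNIP, CXCL8, KRTAP2-3, SMIM11, ANGPTL4, ARRDC4, THBD and MALAT1 rose most (log2 fold changes 1.45 to 3.34), and TUBA1B-AS1, PEDS1-UBE2V1, HTR2A, MT-ATP8, SRCAP, ITGB8, FAM13B and TRANK1 fell most (-10.62 to -1.44). SMIM11 lost its call without vehicle replicate 2 (adjusted p = 0.179), MALAT1 and SRCAP without high replicate 1 (adjusted p = 0.180 and 0.224), PEDS1-UBE2V1 without high replicate 1 (adjusted p = 0.0792) and ANGPTL4 without vehicle replicate 2 (adjusted p = 0.0505).

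Among 7 AhR targets, 5 (ALDH3A1, CYP1A1, TIPARP, NQO1 and ALDH1A3) rose, 0 fell and 2 did not pass, the same adjusted over the list alone. For AhR targets the median log2 fold change was 0.70 (adjusted p = 0.00103, adjusted p = 0.0171 with an estimated correlation). ALDH1A3 and ALDH3A1, aldehyde dehydrogenases, had log2 fold changes of 1.19 and 1.16. NF-kB inflammatory genes had a median log2 fold change of 0.38 (adjusted p = 2.7e-04, adjusted p = 0.00816 with an estimated correlation). Of 18, 6 were higher, 1 (TNFAIP2) lower and 11 not past the threshold, or 7 higher and 1 lower adjusted over the list alone. CXCL3 had a log2 fold change of 1.41. The list of mitochondrially encoded genes (adjusted p = 3.0e-07, adjusted p = 0.195 with an estimated correlation) had a median log2 fold change of -1.13. Its calls were 0 of 13 higher, 11 lower and 2 neither, the same adjusted over the list alone. The mitochondrial share of counts here was 5.85% ± 0.501 (SD, n = 3), and 7.82% ± 0.550 (SD, n = 3) at the low dose.

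The count of 2844 fell to 1796 and 1767 without vehicle replicates 2 and 3 and to 1669 and 1612 without high replicates 1 and 3. Of 33 named genes 12 lost the call in some refit, 11, 2 and 10 without high replicates 1, 2 and 3 and 8, 11 and 8 without vehicle replicates 1, 2 and 3. Within set 13, high against low dose called 398 genes higher and 510 lower, or 591, 527, 521 and 598 in total without high replicate 1, high replicate 3, low replicate 1 and low replicate 3. TXNIP, CXCL8 and ANGPTL4 rose most (log2 fold changes 1.66 to 3.24) and CLIC3, MT1E and BMP4 fell most (-1.49 to -1.34). ANGPTL4 lost the call without low replicate 3 (adjusted p = 0.0968), and also without high replicate 1 or low replicates 1 and 2. The medium dose called 473 genes and the low dose 471. All 6 refits without 1 library moved both counts by more than 1.5 times. Ranges were 53 (without medium replicate 3) to 268 and 68 (without vehicle replicate 3) to 293.

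Guibi-tang, a formula that contains both Polygalae Radix and Aucklandiae Radix, was compared with vehicle at its high dose. Most listed matrix, contractile target, heat shock chaperone and mitotic genes were lower, and HMOX1, GDF15, RND3 and THBD were higher. RND3 (ENSG00000115963, chromosome 2 from 150468195 to 150539011) was at 607 ± 53.1 CPM (SD, n = 3) against 59.6 ± 2.39 (SD, n = 3) in vehicle (log2 fold change 3.35, SE 0.17, adjusted p = 7.8e-20). THBD (ENSG00000178726, chromosome 20 from 23045633 to 23049741), thrombomodulin, was at 92.7 ± 1.41 CPM (SD, n = 3) against 9.16 ± 1.21 (SD, n = 3) (log2 fold change 3.34, SE 0.19, adjusted p = 1.3e-18), and HMOX1 was at 637 ± 18.3 CPM (SD, n = 3) against 59.3 ± 1.81 (SD, n = 3) (log2 fold change 3.42, SE 0.36, adjusted p = 1.0e-10). VIM (ENSG00000026025, chromosome 10 from 17228259 to 17237593), vimentin, fell to 781 ± 51.3 CPM (SD, n = 3) from 5219.5 ± 44.9 (SD, n = 3). Higher genes numbered 4350 and lower genes 4940, and refits without 1 library called between 8348 and 8501. All 40 named genes kept the call in those refits. The largest rises were TM4SF19, the pseudogene NMRAL2P, HMOX1, GDF15, RND3, THBD, SIK1 and IFIT2 (log2 fold changes 2.86 to 3.61), and the largest falls TUBA1B-AS1, TNC, KIF20A, TENM2, EPHA3, KLHL4, MAGED1 and COL1A2 (-10.02 to -3.40). At the medium dose HMOX1 had a log2 fold change of 1.46 (adjusted p = 0.00571), RND3 of 0.82 (adjusted p = 0.00112) and COL1A2 of -0.86 (adjusted p = 3.6e-04), and at the low dose none of the 3 passed, with 0.19, 0.20 and -0.33.

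Collagen and matrix genes had a median log2 fold change of -2.18 (adjusted p = 2.1e-18, adjusted p = 0.0313 with an estimated correlation). Of 22, 0 were higher, 22 lower and 0 not past the threshold, the same adjusted over the list alone. Among 16 YAP and SRF contractile targets, 0 rose, 13 fell and 3 did not pass, the same adjusted over the list alone. For YAP and SRF contractile targets the median log2 fold change was -1.80 (adjusted p = 3.2e-09, adjusted p = 8.7e-05 with an estimated correlation). TAGLN and ACTA2, smooth muscle actin, had log2 fold changes of -2.45 and -2.36. The list of heat shock chaperone genes (adjusted p = 6.1e-07, adjusted p = 0.00471 with an estimated correlation) had a median log2 fold change of -1.37. Its calls were 0 of 16 higher, 12 lower and 4 neither, or 0 higher and 13 lower adjusted over the list alone. HSP90AA1 and HSPA8 had log2 fold changes of -2.15 and -2.11. Of 22 G2/M cell cycle genes, 20 fell, 0 rose and 2 passed neither way, the same adjusted over the list alone. With these G2/M cell cycle genes the median log2 fold change was -1.16 (adjusted p = 6.0e-10, adjusted p = 0.0221 with an estimated correlation).

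In high against low dose 4340 genes were higher and 5127 lower. THBD, GDF15 and HMOX1 were the largest rises (log2 fold changes 3.23 to 3.35) and KIF20A, KLHL4 and TNC the largest falls (-3.70 to -3.57). Of Guibi-tang, the medium dose called 997 genes and the low dose 288. In all, 5 of the 6 refits without 1 library moved each count by more than 1.5 times, with ranges of 408 (without medium replicate 2) to 739 and 22 (without low replicate 2) to 216.

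Soyo-san, a formula that contains Menthae Herba, was compared with vehicle at its high dose, where NEAT1 and SIK1 rose and ID3 and LGR6 fell. NEAT1 (ENSG00000245532, chromosome 11 from 65422774 to 65445540), a long noncoding RNA, was at 862 ± 90.6 CPM (SD, n = 2) against 373 ± 19.1 (SD, n = 3) in vehicle (log2 fold change 1.21, SE 0.15, adjusted p = 3.9e-06). NEAT1 and NDUFB1 were also called higher at the low dose of 5 and 7 of 7 extracts, with mean log2 fold changes of 0.65 and 1.26. ID3 (ENSG00000117318, chromosome 1 from 23557918 to 23559794), an inhibitor of DNA-binding proteins that BMP signalling induces, was at 97.1 ± 2.09 CPM (SD, n = 2) against 243 ± 23.2 (SD, n = 3) (log2 fold change -1.32, SE 0.24, adjusted p = 6.0e-04), and LGR6 (ENSG00000133067, chromosome 1 from 202193901 to 202319781), a receptor for R-spondins, at 2.35 ± 0.235 CPM (SD, n = 2) against 6.73 ± 1.29 (SD, n = 3) (log2 fold change -1.51, SE 0.22, adjusted p = 3.5e-05). SIK1, a salt-inducible kinase, had a log2 fold change of 1.09 (adjusted p = 4.9e-04). The calls were 208 higher and 152 lower. BEST1, GDF15, HMOX1, NDUFB1, NEAT1, SQSTM1, ATP2A3 and SIK1 rose most (log2 fold changes 1.09 to 1.80), and LGR6, EGR1, SAMD11, ID3, ATOH8, RASA4B and LINC02593 were among the largest falls (-1.51 to -1.10). Without vehicle replicate 1, 2 or 3 the count of 360 was 198, 186 or 165, and without high replicate 1 or 2 it was 94 or 79. A fit of the compared groups alone called 4501, and fits without length-tilted libraries and with a length covariate 2881 and 2627. Of 29 named genes 17 lost the call in some refit, 14 and 17 without high replicates 1 and 2 and 11 without each of the 3 vehicle libraries. They included HMOX1, SQSTM1 and GDF15 (adjusted p = 0.227, 0.230 and 0.136 without high replicate 2), BEST1, NDUFB1, EGR1 and LINC02593, whereas NEAT1, SIK1, ATP2A3, LGR6, ID3, ATOH8, SAMD11 and RASA4B were among those that kept it.

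NRF2 targets had a median log2 fold change of 0.47 (adjusted p = 6.5e-11, adjusted p = 0.0428 with an estimated correlation). Of 22, 3 (HMOX1, SQSTM1 and TXNRD1) were higher, 0 lower and 19 not past the threshold, or 15 higher and 0 lower adjusted over the list alone. Among 21 interferon response genes, 2 (RSAD2 and IFI44) rose, 0 fell and 19 did not pass, or 4 higher and 0 lower adjusted over the list alone. For interferon response genes the median log2 fold change was 0.28 (adjusted p = 1.4e-04, adjusted p = 0.0425 with an estimated correlation). RSAD2 and IFI44 lost the call in some refits (adjusted p up to 0.657 and 0.361). Of 16 YAP and SRF contractile targets, 3 (among them SRF and CCN2) fell, 0 rose and 13 passed neither way, or 4 lower and 0 higher adjusted over the list alone. With these YAP and SRF contractile targets the median log2 fold change was -0.15 (adjusted p = 0.00379, adjusted p = 0.0407 with an estimated correlation). High against low dose called 29 genes higher and 32 lower. The immediate early gene FOSB was at 6.6 ± 0.216 CPM (SD, n = 2) against 2.49 ± 0.312 (SD, n = 2) at the low dose (log2 fold change 1.41, SE 0.21, adjusted p = 2.4e-04), and ID2 at 13.7 ± 0.437 CPM (SD, n = 2) against 30.6 ± 4.29 (SD, n = 2) (log2 fold change -1.16, SE 0.10, adjusted p = 7.9e-10). ATP2A3 and PLIN2 also rose and ID3 and ATOH8 fell, and all 4 lost the call without some library, with adjusted p = 0.286 for ATP2A3 without high replicate 2, 0.400 for PLIN2 without low replicate 2, 0.448 for ID3 without low replicate 1 and 0.151 for ATOH8 without high replicate 2. The count of 61 became 19, 6, 17 and 15 without high replicates 1 and 2 and low replicates 1 and 2. Its medium dose called 36 genes and the low dose 177. Both counts moved by more than 1.5 times in all 5 refits without 1 library.

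Okbyeongpung-san, a formula that contains Saposhnikoviae Radix, had 1 library per dose, so its 3 libraries were pooled as 1 group against vehicle and no dose was tested. PADI2 (ENSG00000117115, chromosome 1 from 17066761 to 17119435), a citrullinating enzyme, was at 4.50 ± 1.87 CPM (SD, n = 3) against 9.27 ± 0.233 (SD, n = 3) in vehicle (log2 fold change -1.03, SE 0.18, adjusted p = 8.8e-04). The high-dose library gave the highest values of the 4 named rises. GDF15 was at 39.1, 4.64 and 4.93 CPM in the high, medium and low library against a vehicle mean of 3.74, and BEST1 at 35.1, 8.94 and 9.62 against 3.99. EIF3CL, which has a close paralog, and the antisense locus PXN-AS1 were the other rises, and EGR1, BCORL1, PADI2 and SLC35E2A the falls (log2 fold changes -1.75 to -0.97). The pooled test called 963 genes higher and 460 lower. The count of 1423 became 33, 2440 and 3070 without the high, medium and low library, and 599, 491 and 277 without vehicle replicates 1, 2 and 3. Without the high library 7 of 8 named genes lost the call, EGR1 at a log2 fold change of -1.41 (adjusted p = 0.0962) and GDF15 at 0.35 (adjusted p = 0.644), and 2, 2 and 3 lost it without vehicle replicates 1, 2 and 3. PADI2 kept it in those refits, but in a fit of the 6 compared libraries alone all 8 lost it. Among 22 NRF2 targets, 15 rose, 0 fell and 7 did not pass, or 17 higher and 0 lower adjusted over the list alone. For NRF2 targets the median log2 fold change was 0.60 (adjusted p = 1.3e-08, adjusted p = 0.339 with an estimated correlation). In this pooled group 9 of 28 lists were called, of which 0 held with an estimated correlation and 6 with fry.

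**Figure D3:**
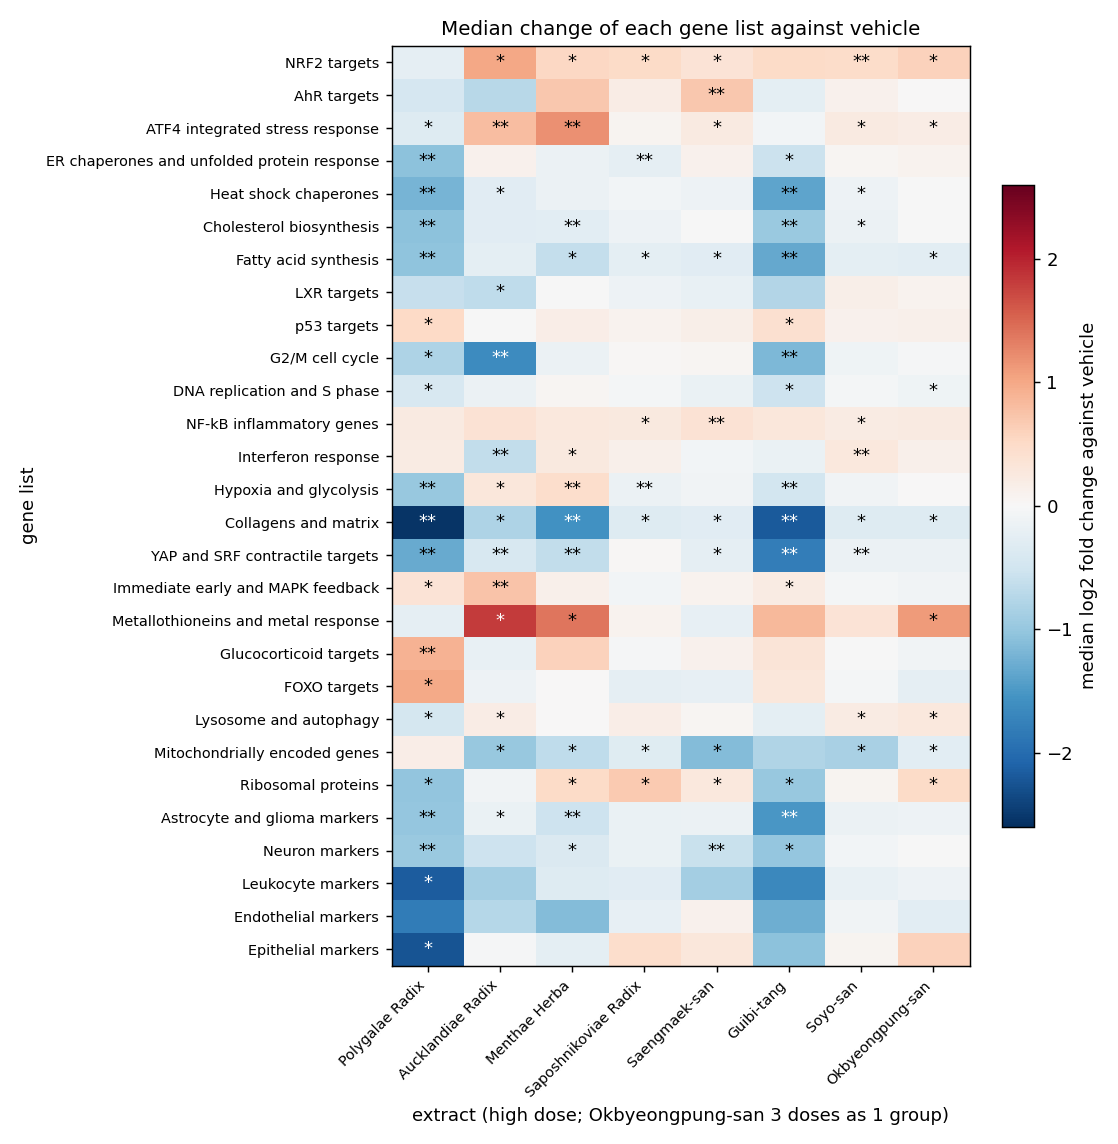
Median log2 fold change against vehicle of each fixed list (1 line per list) at the high dose of 7 extracts and in the pooled Okbyeongpung-san libraries (1 column each), with * for adjusted p under 0.05 and ** where an estimated correlation also gives a call. Collagen and matrix genes have medians of -2.55 for Polygalae Radix, -2.18 for Guibi-tang and -1.56 for Menthae Herba.

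The high dose of Soyo-san was set against that of its constituent Menthae Herba, at the same concentration, to see how formula and herb differ. Soyo-san was higher in 1033 genes and lower in 326. The count of 1359 became 861 without Menthae Herba high replicate 3 and 667 and 672 without Soyo-san high replicates 1 and 2. The extracts come from sets 14 and 12, so extract and set cannot be told apart.

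Changes from low to high dose, which use no vehicle library, were compared between formulas and herbs, to see whether a formula resembles the herbs in it. Guibi-tang and Polygalae Radix shared 2881 genes higher in both (880.1 for independent calls) and 3945 lower in both (1287), and 52 went opposite ways (2129). Guibi-tang and Aucklandiae Radix shared 1013 higher (420.0) and 1494 lower (672), with 439 opposite (1065). Soyo-san and Menthae Herba shared 11 higher (1.48) and 27 lower (2.77), with 6 opposite (4.15). Of pairs without a constituent, Soyo-san and Aucklandiae Radix shared 14 higher (2.81) and 23 lower (4.20), Saengmaek-san and Aucklandiae Radix 150 higher (38.5) and 244 lower (66.9), and Guibi-tang and Menthae Herba 301 higher (221) and 861 lower (445). Pearson r of the log2 fold changes across the 18601 genes was 0.796 for Guibi-tang and Polygalae Radix, 0.442 for Guibi-tang and Aucklandiae Radix, 0.150 for Soyo-san and Menthae Herba, and -0.148 for Okbyeongpung-san and Saposhnikoviae Radix. The Soyo-san value ran from -0.0931 (without replicate 2) to 0.317 (without replicate 1). Genes are not independent replicates. The mean of these 4 constituent pairs was 0.310, and of the 24 ways to reassign the 4 herbs a share of 0.25 gave a mean at least as high (exact permutation test, one-sided, p = 0.25, smallest reachable p = 0.0833), so the test could not reach 0.05. The median over reassignments was 0.228 and the highest 0.439. Okbyeongpung-san had r = 0.514 with Menthae Herba, which it does not contain, and in both a high library was length-tilted. With herbs they lack Guibi-tang had 0.0774 (Menthae Herba) and 0.154 (Saposhnikoviae Radix) and Soyo-san 0.144 (Aucklandiae Radix), and Saengmaek-san had r of 0.125, 0.180, 0.0564 and 0.181 with the 4 herbs in the order above. In this family 16 correlations across genes were computed.

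Marker lists of cell types were measured in every comparison. Astrocyte and glioma markers at the high dose of Polygalae Radix had a median log2 fold change of -1.0 (adjusted p = 2.5e-04, adjusted p = 0.0233 with an estimated correlation). Of 9, 0 were higher, 7 lower and 2 not past the threshold, the same adjusted over the list alone. VIM and the stem cell filament NES had log2 fold changes of -3.04 and -2.40. Among 5 neuron markers there, 0 rose, 4 (SYT1, MAP2, SNAP25 and TUBB3) fell and 1 did not pass, the same adjusted over the list alone. For neuron markers there the median log2 fold change was -0.96 (adjusted p = 0.0148, adjusted p = 0.0419 with an estimated correlation). Of 4 leukocyte markers 3 (PTPRC, CD68 and CSF1R) fell there (adjusted p = 0.0306, adjusted p = 0.0751 with an estimated correlation), and of 4 epithelial markers 4 (KRT18, KRT8, KRT19 and KRT14) fell (adjusted p = 0.0357, adjusted p = 0.245 with an estimated correlation). Astrocyte and glioma markers were also lower as a list (second p with an estimated correlation) for Aucklandiae Radix (4 of 9 fell, adjusted p = 0.0292 and 0.156), Menthae Herba (4 of 9 fell, adjusted p = 0.00163 and 0.0434) and Guibi-tang (6 of 9 fell, adjusted p = 1.6e-05 and 0.00816). Neuron markers were so for Menthae Herba (2 of 5 fell, adjusted p = 0.0385 and 0.0908), Saengmaek-san (3 of 5 fell, adjusted p = 0.01 and 0.0313) and Guibi-tang (4 of 5 fell, adjusted p = 0.0292 and 0.0737). Endothelial markers, 3 tested, passed at no high dose, with adjusted p = 0.208 for Polygalae Radix, and of 8 hepatocyte markers 2 passed the filter, too few to test.

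**Figure D4:**
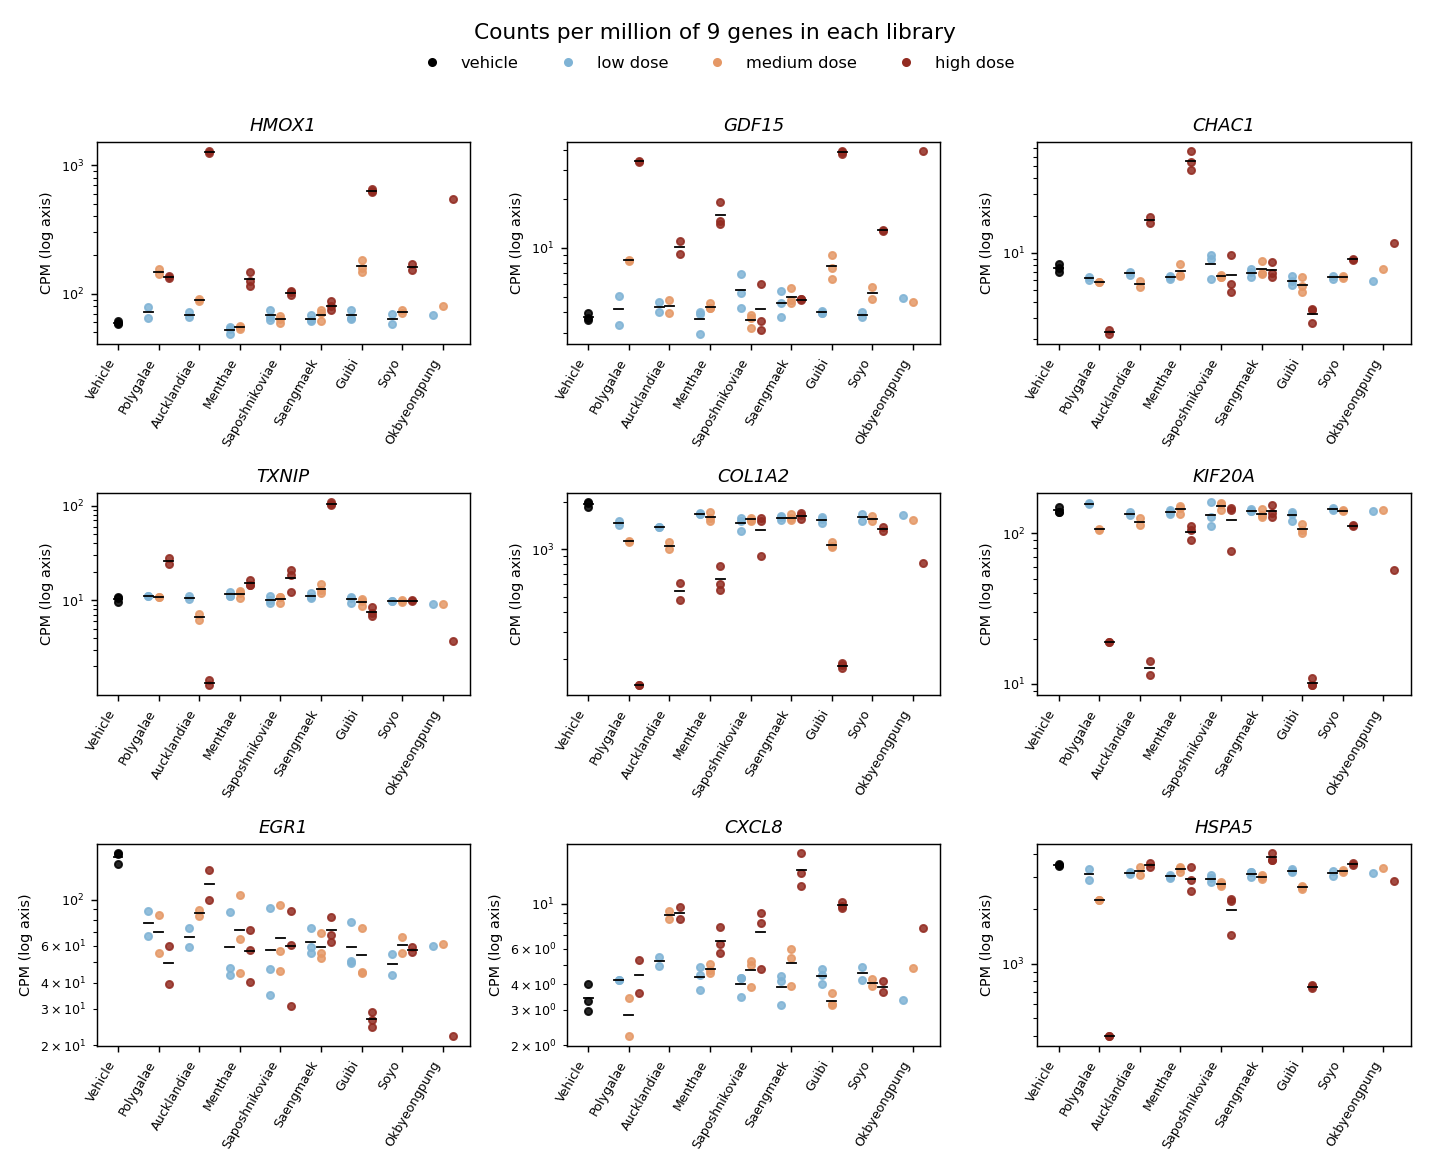
Scaled counts (CPM, log axis) of HMOX1, GDF15, CHAC1, TXNIP, COL1A2, KIF20A, EGR1, CXCL8 and HSPA5 in each library, 1 point per library, by extract and coloured by dose, with a line at the mean of each group. HMOX1 means reach 1270.0 at the high dose of Aucklandiae Radix and 637 at that of Guibi-tang, against 59.3 in vehicle.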

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

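All contrasts in this part were chosen only after the result of each extract was seen, and the genes named with them were chosen after their values were seen. Each contrast tests, in the same edgeR fit, whether the change from low to high dose differed between 2 extracts, so no vehicle library enters. Polygalae Radix and Aucklandiae Radix, both in set 11, differed in 6077 genes, 2737 with a higher value for Polygalae Radix and 3340 with a lower one, and 774 of them went opposite ways with a call in each. TXNIP differed by 4.21 (adjusted p = 6.4e-14) and ASNS, an asparagine synthetase, by -3.82 (adjusted p = 9.4e-12). Guibi-tang differed from Aucklandiae Radix in 4720 genes (2033 higher, 2687 lower, 439 opposite). EPRS1, a transfer RNA synthetase, differed by -2.92 (adjusted p = 8.1e-21) and IFIT2 by 3.32 (adjusted p = 6.0e-10). Guibi-tang differed from Polygalae Radix in 626 genes (375 higher, 251 lower, 52 opposite), with THBD at 2.62 (adjusted p = 3.8e-08) and CCN2, a target of YAP, at -1.67 (adjusted p = 2.3e-06). Without Polygalae Radix high replicate 2, low replicate 2 or low replicate 3 that count was 349, 417 or 349. Soyo-san differed from Menthae Herba in 489 genes (379 higher, 110 lower, 6 opposite), with the stress genes CHAC1 at -2.66 (adjusted p = 9.1e-08), DDIT4 at -2.42 (adjusted p = 6.6e-07) and SESN2 at -1.63 (adjusted p = 7.5e-13). Without Soyo-san high replicate 1, high replicate 2 or low replicate 1 the count was 259, 255 or 202. The doses of Polygalae Radix and Aucklandiae Radix in µg/mL were below those of the formulas, so dose and content were not separated, and no cause of these differences was tested.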

How the results depend on the processing

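The transcript-length slope with its limit, the settings built on it, thinned libraries, the 4 difference contrasts and the refits on other sample splits were chosen after the data were examined. The model, comparisons, gene lists, thresholds, rule for named genes and all other alternatives were chosen before the data were examined. No named gene and no called list reversed its direction under any alternative run. Of 316 named-gene results, 0 lost the call with RLE size factors, 2 with a replicate block, 6 with DESeq2, 12 with the covariate, 16 without the length-tilted libraries and 55 without the low-count filter. In fits of the compared groups alone 51 of 313 did, with library-name set by replicate as a block 2 of 42, and in at least 1 refit without 1 library 82 of 316. Within a set, deviations from the group mean had a median r of 0.0537 between libraries of the same replicate number and -0.0439 between different ones. Over the 184 list calls, an estimated correlation ended 99, fry 14, the length-tilted libraries 7 and the block 0. The number of lists called went from 89 to 37 against vehicle and from 95 to 48 between high and low dose with an estimated correlation, and to 134 against vehicle with fry, which does not compare a list with other genes. Lists were not refitted without single libraries. The mean formula and herb correlation of 0.310 was 0.355 for genes above the higher expression limit, 0.322 as Spearman rho, 0.708 from high minus vehicle, where shared vehicle libraries also gave a median of 0.505 over reassignments, and between 0.0821 and 0.507 without 1 replicate number. Its exact p ran from 0.0833, the smallest reachable, to 0.667, so no setting could pass. Set by replicate as a block moved 0 of 7 counts by more than 1.5 times.

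The counts of called genes moved more, and the cause was not tested unless it follows from the setting. With RLE size factors 2 of 34 counts moved by more than 1.5 times. Aucklandiae Radix had 34 (low) and Soyo-san 23 (medium). With a replicate block 1 of 34 moved. Soyo-san had 316 (low). DESeq2 moved 17 of 34 counts. Polygalae Radix had 308 (low), and Aucklandiae Radix 872 (medium) and 284 (low). Menthae Herba had 245 (medium) and 198 (low), and Saposhnikoviae Radix 2174 (high), 317 (medium), 2914 (low) and 123 (high against low dose). Saengmaek-san had 825 (medium) and 810 (low), and Guibi-tang 656 (low). Soyo-san had 563 (high), 141 (medium), 468 (low) and 116 (high against low dose), and the difference Soyo-san and Menthae Herba 736. Without the low-count filter, where more genes enter the adjustment, 25 of 34 moved. Polygalae Radix had 197 (medium) and 2 (low), and Aucklandiae Radix 123 (medium) and 5 (low). Menthae Herba had 17 (medium), 8 (low) and 1616 (high against low dose), and Saposhnikoviae Radix 222 (high), 12 (medium), 489 (low) and 1 (high against low dose). Saengmaek-san had 1512 (high), 66 (medium), 75 (low) and 384 (high against low dose), and Guibi-tang 298 (medium) and 22 (low). Soyo-san had 114 (high), 5 (medium), 12 (low) and 32 (high against low dose), and Okbyeongpung-san 367. Soyo-san against Menthae Herba had 775, and the differences 243 (Guibi-tang and Polygalae Radix) and 186 (Soyo-san and Menthae Herba).

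Fits of the compared groups alone estimate the spread from at most 6 libraries, or 10 for the differences, and 25 of 34 counts moved. Polygalae Radix had 2693 (medium) and 2005 (low), and Aucklandiae Radix 9263 (high), 3178 (medium), 4257 (low) and 7236 (high against low dose). Menthae Herba had 1821 (high), 2738 (medium), 2550 (low) and 874 (high against low dose), and Saposhnikoviae Radix 0 (high), 3667 (medium), 1 (low) and 0 (high against low dose). Saengmaek-san had 5218 (high), 3634 (medium) and 5007 (low), and Soyo-san 4501 (high), 1946 (medium), 1814 (low) and 37 (high against low dose). Okbyeongpung-san had 0 and Soyo-san against Menthae Herba 0. The difference Guibi-tang and Aucklandiae Radix had 7486, and the difference Soyo-san and Menthae Herba 121. For the count of 0 with Saposhnikoviae Radix high against vehicle, edgeR had 828 genes at unadjusted p under 0.05 and DESeq2 called 74 in the same libraries, for the 0 of high against low dose the numbers were 167 and 5, and for Okbyeongpung-san 1285 and 93. For the 0 of Soyo-san against Menthae Herba they were 1819 and 526.

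Without the 10 length-tilted libraries 27 of 34 counts moved, and the low dose of Saposhnikoviae Radix kept 1 library, assumed to vary like the other groups. Polygalae Radix had 3345 (medium) and 2319 (low), and Aucklandiae Radix 9576 (high), 3412 (medium), 2733 (low) and 7960 (high against low dose). Menthae Herba had 1787 (medium), 1444 (low) and 4095 (high against low dose), and Saposhnikoviae Radix 2012 (medium) and 337 (low). Saengmaek-san had 5958 (high), 4330 (medium), 3766 (low) and 2475 (high against low dose), and Guibi-tang 3217 (medium) and 962 (low). Soyo-san had 2881 (high), 1369 (medium), 2753 (low) and 465 (high against low dose), and Okbyeongpung-san 862. Soyo-san against Menthae Herba had 2912. The differences had 2926 (Guibi-tang and Polygalae Radix), 8195 (Guibi-tang and Aucklandiae Radix), 1846 (Soyo-san and Menthae Herba) and 9809 (Polygalae and Aucklandiae Radix). With the transcript-length slope as a covariate 28 of 34 moved. Polygalae Radix had 3346 (medium) and 2351 (low), and Aucklandiae Radix 9573 (high), 3707 (medium), 2243 (low) and 7980 (high against low dose). Menthae Herba had 7014 (high), 1752 (medium), 1553 (low) and 5155 (high against low dose), and Saposhnikoviae Radix 2219 (medium) and 1054 (high against low dose). Saengmaek-san had 6659 (high), 2219 (medium), 2836 (low) and 4044 (high against low dose), and Guibi-tang 4455 (medium) and 3105 (low). Soyo-san had 2627 (high), 1490 (medium), 3013 (low) and 403 (high against low dose), and Okbyeongpung-san 2904. Soyo-san against Menthae Herba had 3641. The differences had 3243 (Guibi-tang and Polygalae Radix), 8412 (Guibi-tang and Aucklandiae Radix), 2228 (Soyo-san and Menthae Herba) and 9772 (Polygalae and Aucklandiae Radix). Thinned to the smallest library, Saposhnikoviae Radix had 68 genes at the medium and 1786 at the low dose.

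Leaving out 1 library moved 26 of 34 counts by more than 1.5 times in at least 1 refit. Ranges give the lowest and highest count. Polygalae Radix had 207 to 417 (medium) and 5 to 30 (low), and Aucklandiae Radix 86 to 307 (medium) and 1 to 11 (low). Menthae Herba had 2459 to 4080 (high), 16 to 41 (medium), 8 to 34 (low) and 1487 to 2853 (high against low dose), and Saposhnikoviae Radix 209 to 4358 (high), 21 to 34 (medium), 93 to 5501 (low) and 7 to 218 (high against low dose). Saengmaek-san had 1612 to 2863 (high), 53 to 268 (medium), 68 to 293 (low) and 521 to 619 (high against low dose), and Guibi-tang 408 to 739 (medium) and 22 to 216 (low). Soyo-san had 79 to 198 (high), 1 to 12 (medium), 8 to 53 (low) and 6 to 19 (high against low dose), and Okbyeongpung-san 33 to 3070. Soyo-san against Menthae Herba had 667 to 1500. The differences had 349 to 522 (Guibi-tang and Polygalae Radix) and 202 to 673 (Soyo-san and Menthae Herba). These refits kept the gene set and trended dispersions of all libraries and renewed scaling factors and quasi-likelihood dispersions, and where a dose had 2 libraries the lone one left was assumed to vary like the other groups. High doses called more genes than were changed in the simulation, so its recovery rates may not hold for them.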

Other observations

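Refits of other sample splits, the high minus medium test and the settings for length and thinning were chosen only after the results were seen. So were the genes listed in this part beyond those named for the high doses. What each other test would show was set out before its result was seen. EGR1, an immediate early transcription factor, was lower than in vehicle in all 22 comparisons with vehicle, that of pooled Okbyeongpung-san among them, with log2 fold changes from -2.58 (Guibi-tang high) to -0.42 (Aucklandiae Radix high, adjusted p = 0.458), and it was called in 13 of them. Vehicle stood at 159.9 ± 10.4 CPM (SD, n = 3), and the shared vehicle libraries make these comparisons dependent.

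EGR1 and NR1D1, a clock repressor, belong to 141 genes called in the same direction at the low dose of at least 4 of 7 extracts, 114 higher and 27 lower, with mean log2 fold changes of -1.39 and -0.80, while ANKRD1 had 0.68. Independent lists would share 0.00816 genes, and in 20 simulated sets that shared the vehicle libraries and drew each gene independently the median number was 0 and the highest 0. The median shift was 0.45, and the median high minus low change in its direction, a share of -0.331, decides nothing, since the low-dose libraries that chose the genes enter it. The high minus medium change, which uses none of the libraries that chose them, had a median share of -0.216, with log2 medians from -0.34 to 0.10 by extract, which argues against a response that grows with dose. A difference between the vehicle set and the extract sets, a library-wide shift of the 3 vehicle libraries, and anything that handling with any extract does stay open, since these libraries of 1 set cannot be split by set.

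Saposhnikoviae Radix had 1899 genes called at the low dose and 94 at the medium dose, a ratio of 20.2. Low replicates 2 and 3 were length-tilted, and leaving out 1 library gave low-dose counts from 93 (without low replicate 3) to 5501 (without low replicate 1). With thinned libraries the low dose kept 1786 genes and the ratio was 26.3, which argues against library size. With the length slope as a covariate the counts were 2140 and 2219, a ratio of 0.964. The ratio fell because the medium count rose while the low one did not fall, so length-dependent signal stays open. A response to the low dose stays open too. Of 5501 genes called with replicates 2 and 3, 69.9% had replicate 1 on the called side of the medium-dose mean, between the limits set. Its slope (-0.0617) also lay below the medium ones (lowest -0.0403), so this share decides nothing.

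The mean correlation between formulas and their constituent herbs was 0.310. In 3 of 4 pairs both doses keep a library without the length-tilted ones, with a mean of 0.462 before and 0.465 after. The positive high-dose slopes of Polygalae Radix and Guibi-tang stayed in. The remaining pair, Okbyeongpung-san and Saposhnikoviae Radix, had tilted libraries on both sides, with r from -0.695 without replicate 2 to 0.545 without replicate 3. So length-dependent signal stays open. A share of 0.25 of the 24 reassignments of herbs gave as high a mean, while the real one was the highest (exact permutation p = 0.0833, the smallest reachable) from high minus vehicle, without replicate 3 and, with the remaining pair missing, without replicate 1 or the length-tilted libraries. Since the test cannot reach 0.05, likeness of a formula to its own herbs cannot be told from general likeness of responses. Dose differences stay open too.

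Refits on 6 libraries alone of the comparisons with 3 libraries against 3 have 10 splits, too few for a share under 0.05. The real split and the highest other one called 1821 and 0 genes for Menthae Herba high, 2738 and 1 for medium and 2550 and 1 for low, 5218 and 0 for Saengmaek-san high, 3634 and 1 for medium and 5007 and 0 for low. Guibi-tang gave 12324 and 0 for high, 1007 and 3 for medium and 304 and 0 for low, and Saposhnikoviae Radix 3667 and 1 for medium and 1 and 0 for low. High against low dose gave 874 and 0 for Menthae Herba, 1044 and 0 for Saengmaek-san and 10995 and 0 for Guibi-tang. In each of these 1 of the 10 splits, the real one, gave as many genes. For Saposhnikoviae Radix high and for Okbyeongpung-san the real split called 0 genes with edgeR and the highest other 0, so 10 of 10 splits gave as many, with 828 and 1285 genes at unadjusted p under 0.05 and 74 and 93 called by DESeq2. For Saposhnikoviae Radix low against vehicle, edgeR's 1 stood beside 5463 at unadjusted p and 2893 by DESeq2. For Saposhnikoviae Radix high against low dose the real split called 0 genes with edgeR (167 at unadjusted p under 0.05, 5 by DESeq2), 10 of 10 splits gave as many or more, and the split of the 3 length-tilted libraries from high replicates 1 and 3 and low replicate 1 called 6220, which points to a structure of the samples that the doses do not describe.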
